A study of Rattus norvegicus with 28 samples.

How the data were processed

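RNA was sequenced from the spinal cord and brain of wild-type rats and of rats labelled mtCO3mut, in which cytochrome c oxidase, respiratory complex IV, was made deficient in neurons by editing mitochondrial DNA. The labels list 28 samples in 6 groups. Spinal cord and brain each have 4 mtCO3mut and 4 wild-type samples, and an early-stage spinal cord set has 6 of each. Per the labels' protocols, ribosomal RNA was depleted from 2 µg of total RNA, strand-marked libraries were made with dUTP, and paired 150-base reads were sequenced. The submitters' processing notes name cutadapt, featureCounts, DESeq2 and the rat build mRatBN7.2, without versions or settings. The aligner and the strand setting of the counting are not given in the sources used here. Reads shared between near-identical or overlapping genes may therefore have been assigned in ways that the counts do not show.

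The deposited tables hold raw counts per gene made by the authors, whole numbers with no normalization, for 30560 Ensembl gene identifiers in each of the spinal cord and brain tables. The spinal cord table is titled as lumbar. The labels do not say whether samples of one group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

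The columns of both tables carry a plus or a minus mark and a number, not a genotype. Plus was read as mtCO3mut and minus as wild type. This is a reading of the names that neither the labels nor the tables state. Libraries are therefore called plus-marked or minus-marked throughout, and every direction is plus against minus. If the genotypes were the other way round in both tables, each direction would reverse against the genotype. Counts of genes, sizes and the comparison of tissues would then stay as given. If the marks stood for something else, or differed in meaning between the tables, the results would not compare the genotypes as described. Libraries are numbered 1 to 4 within a mark, and the same name stands for the same number in both tissues. The early-stage table has 12 columns whose names could not be tied to a genotype; they were not used here, so early-stage spinal cord and its comparison with later spinal cord were not analysed here.

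The tables do not pair identifiers with gene names. The reference table used here gave an Ensembl identifier for 0 of its 47357 genes, so no identifier could be matched to a name. The edited gene, which was to be reported first as a check of the labels, was therefore not examined, and none of the 51 gene lists fixed before the data were examined was tested. No coordinates are given for the same reason. The naming rule took genes with an adjusted p under 0.05, a mean log2 CPM of at least 0 and no overlap between the marks in CPM, ordered by fold change, and left out genes that have only an identifier. That exclusion would have removed every gene. It was lifted after the tables were seen, and the list was shortened to the first gene in each direction per tissue.

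Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr, libraries were scaled by TMM, and each tissue was fitted separately on mark alone with the robust quasi-likelihood F test. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference between the tissues in the effect of mark was tested as the interaction term in a joint fit of all 16 libraries, treated as independent. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Fold changes of both tissues were compared by correlation across genes, which are not independent replicates, with an exact test over the 70 ways of assigning the brain marks.

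Alternatives set before the data were examined were RLE and upper-quartile scaling, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 1 CPM, an absolute log2 fold change of at least 1, a block by number for the interaction, and leaving out each library. Alternatives added after the data were seen were library sizes without the 10 most abundant genes, the lane-like code in the column names as a term or as a subset (in spinal cord L24 against the other 4 codes together, since those hold 1 library each), and counts thinned to the smallest library.

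The fits were tested on simulated data with known fold changes in 200 genes. In the spinal cord simulation, run on 16910 genes, edgeR recovered 29.8% of genes changed 1.5-fold and 83.3% of those changed 2-fold, and 3.52% of its calls were false. In the brain simulation, run on 16707 genes, it recovered 50.0% and 83.7%, with 6.79% false calls. In the interaction simulation, run on 16180 genes, it recovered 15.9% and 62.5%, with 4.35% false calls. DESeq2 made 19.8% false calls in the spinal cord simulation on 17134 genes and 18.1% in the brain simulation on 16860 genes. The simulated fits took only genes that passed filterByExpr, whereas the DESeq2 fits of the real data took all 30560 genes. The number of genes that truly differ in the real data is also unknown. These false shares therefore do not carry over as rates to its larger counts below in these tissues, which are still to be read with caution. The simulated counts were drawn with dispersions estimated by edgeR, and DESeq2 was not run on the interaction simulation.

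Total counts ranged from 21008418 to 47597097 per spinal cord library and from 33105800 to 82776333 per brain library. Replicate pairs of one group differed by 18.99 to 347.4 in chi-square per gene, against 1 for counting noise alone, so no replicate of a group was a copy of another of that group; pairs across groups were not compared.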

Results

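Gene counts were compared between plus-marked and minus-marked libraries of rat spinal cord and brain, with 4 libraries of each mark in each tissue. The design asks what a deficiency of cytochrome c oxidase in neurons does to gene expression in these tissues. Plus was read as mtCO3mut and minus as wild type from the names of the columns alone. In spinal cord, total counts had a median of 33030880 (21008418 to 40359757) in the plus-marked and 41514808 (39952615 to 47597097) in the minus-marked libraries. In brain, the medians were 68768265 (64782608 to 82776333) and 46528486 (33105800 to 62851529), so every plus-marked brain library was deeper than every minus-marked one. Genes with at least 1 count numbered 19712 ± 530 and 19960 ± 82.8 in plus- and minus-marked spinal cord, and 19612 ± 187 and 19009 ± 284 in brain (mean ± SD, n = 4).

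The marks separated along the first principal component in spinal cord and not in brain. In spinal cord this component held 34.6% of the variance of log2 CPM. The plus-marked libraries lay between 13.05 and 60.97 on it and the minus-marked ones between -36.87 and -26.42, a difference in means with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow. Plus-marked library 2 lay farthest out and was also the shallowest spinal cord library, at 21008418 counts. In brain the first component held 21.8% of the variance, and the difference in means had an exact two-sided permutation p of 0.143.

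**Figure D1:**
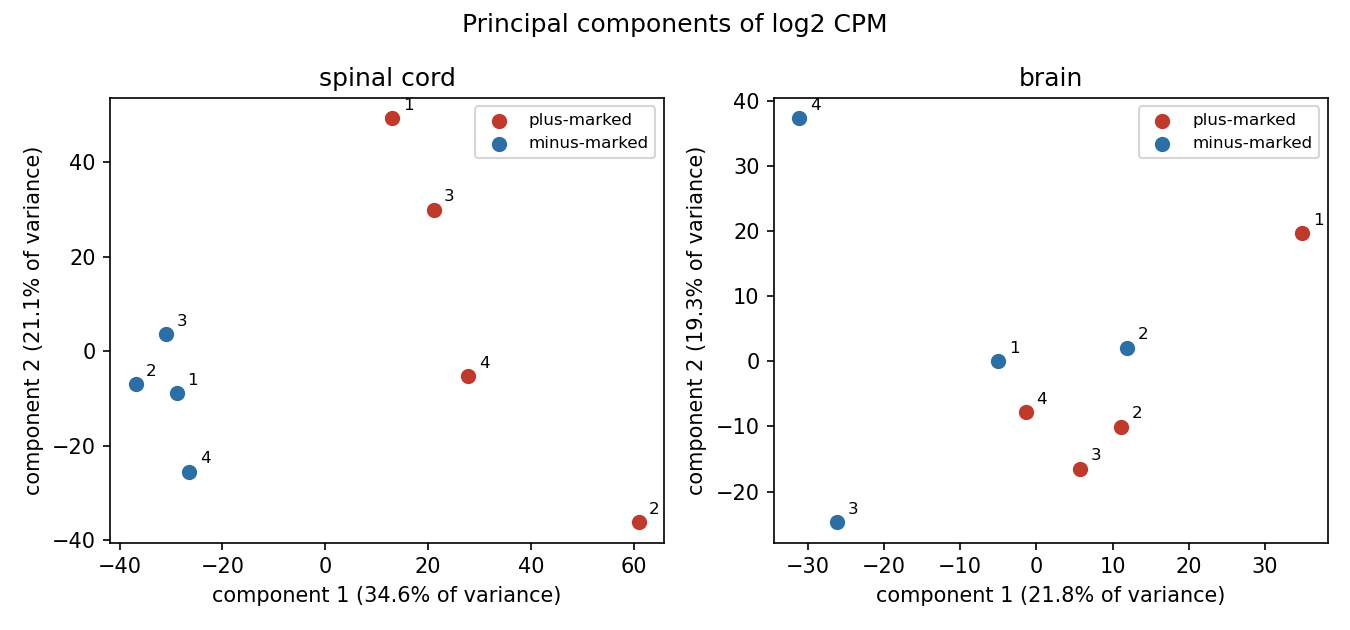
Each point is a library on the first and second principal components of log2 CPM (arbitrary units, share of variance on each axis), for spinal cord on the left and brain on the right, coloured by mark and numbered within mark. The spinal cord marks do not overlap on component 1, whereas the brain marks do, and brain minus-marked library 4 lies apart at 37.32 on component 2.

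In spinal cord, 2312 of 17134 genes tested (13.5%) differed between the marks. Of these, 1171 were higher and 1141 lower in the plus-marked libraries, a near-even balance that turned under some alternatives (1115 and 1237 without the 10 most abundant genes in library sizes, 1051 and 1168 with no filter on low counts), with a median absolute log2 fold change of 0.61. Large changes were mostly increases: of the 543 called genes with an absolute log2 fold change of at least 1, 419 were higher and 124 lower. ENSRNOG00000022242 rose most under the naming rule, from 1.29 ± 0.538 CPM in minus-marked to 19.6 ± 14.4 CPM in plus-marked libraries (SD, n = 4), a log2 fold change of 3.92 (SE 0.56, edgeR adjusted p = 0.00294). All 4 plus-marked libraries lay above all 4 minus-marked ones, but they ranged from 6.448 to 40.2 CPM. ENSRNOG00000047175 fell most, from 2.17 ± 0.613 to 0.254 ± 0.17 CPM (SD, n = 4), a log2 fold change of -3.06 (SE 0.46, edgeR adjusted p = 0.00162), again with no overlap between the marks. Its plus-marked libraries were all under 0.5 CPM, and it did not pass the count filter in brain.

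Marks did not overlap for 3462 of the genes tested in spinal cord (20.2%), where chance gives 2.86% on average over all splits. Genes are not independent, and this excess was not tested. The number of genes called depended on single libraries. It was 1463 without plus-marked library 3, and 1341, 1175 and 1398 without minus-marked libraries 1, 2 and 3. Of the 2312 genes, 1004 were called in each of the 8 fits with 1 library left out, 535 higher and 469 lower, and no called gene changed sign in any of them. Libraries of both marks shared the lane-like code L24, 3 plus-marked and 1 minus-marked. Within it 267 genes were called, 198 higher and 69 lower. The other 4 codes hold 1 library each, 1 plus-marked and 3 minus-marked, so mark and code cannot be told apart among them. In these 4 libraries together 1089 genes were called, 396 higher and 693 lower, the opposite balance to that within L24. In both subsets the lone library was taken to vary like the others. With L24 set against all other codes as a term, 2636 genes were called, 1301 higher and 1335 lower. Both fold changes named above fell short of the threshold within L24, with an adjusted p of 0.137 for ENSRNOG00000022242 (log2 fold change 5.03) and 0.0837 for ENSRNOG00000047175 (-3.12). In the libraries of the other codes the log2 fold changes were 2.10 and -2.89, and without plus-marked library 1 they were 3.29 and -3.68. Over all alternatives their adjusted p ranged from 9.58e-09 to 0.137 and from 1.08e-08 to 0.0837.

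In brain, 41 of 16860 genes tested (0.243%) differed between the marks, 32 higher and 9 lower in the plus-marked libraries. The median absolute log2 fold change of these genes was 0.87, and 18 of the 19 with an absolute log2 fold change of at least 1 were higher. ENSRNOG00000046834 rose most, from 7.04 ± 2.15 CPM in minus-marked to 35.8 ± 2.82 CPM in plus-marked libraries (SD, n = 4), a log2 fold change of 2.35 (SE 0.16, edgeR adjusted p = 2.4e-05). This gene was also higher in plus-marked spinal cord, at 106 ± 17.6 against 19.4 ± 5.6 CPM (SD, n = 4), a log2 fold change of 2.44 (SE 0.21, edgeR adjusted p = 0.000154). It passed the threshold in both tissues under every alternative run, with an adjusted p of at most 0.0174 in brain and 0.0254 in spinal cord. ENSRNOG00000019176 fell most in brain, from 3.61 ± 0.647 to 1.56 ± 0.121 CPM (SD, n = 4), a log2 fold change of -1.22 (SE 0.19, edgeR adjusted p = 0.0182). In spinal cord its log2 fold change was -0.81 (SE 0.44, edgeR adjusted p = 0.247), with overlapping marks. With lane-like code L24 set against the others as a term, it was -1.53 with an edgeR adjusted p of 0.0236, and over all alternatives this spinal cord p ranged from 0.0236 to 0.535.

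**Figure D2:**
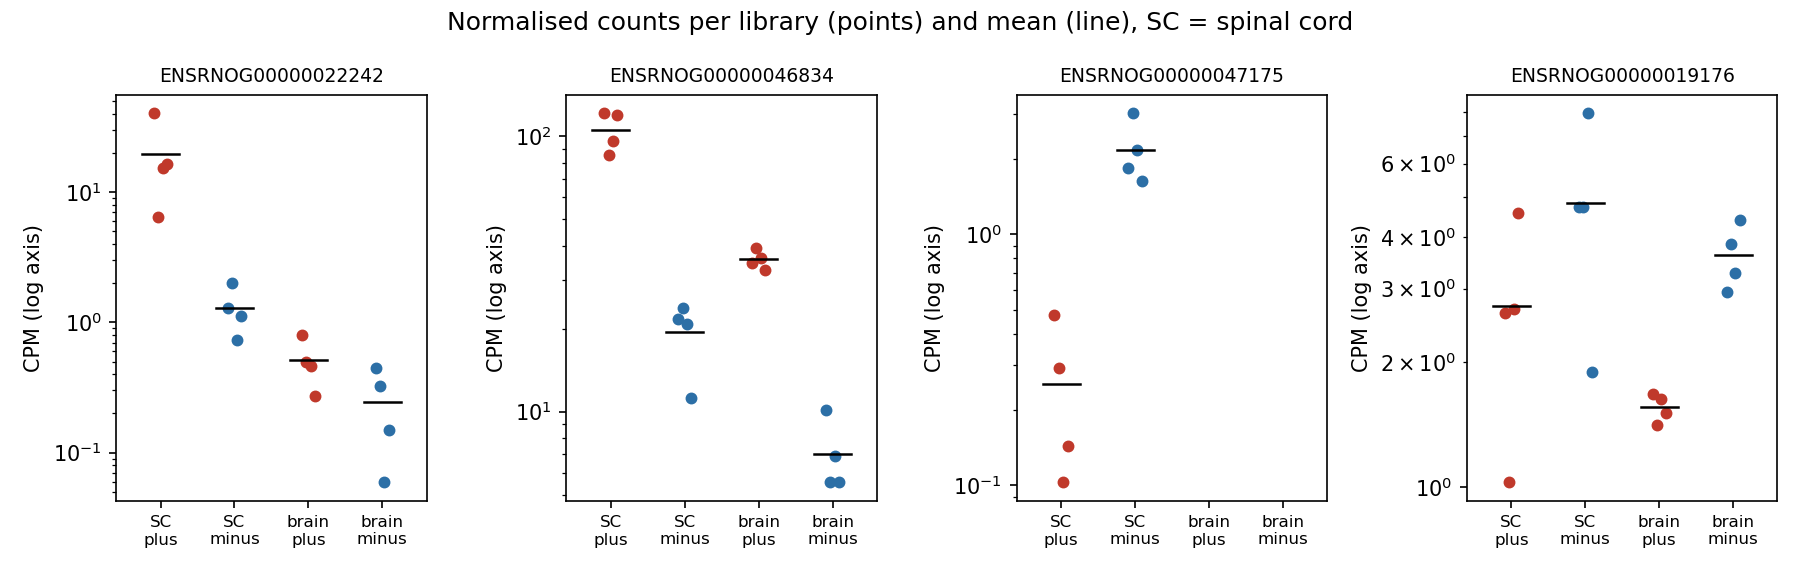
Points are TMM-scaled CPM of single libraries on a log axis and lines are means of 4 libraries, for the 4 genes named, in plus- and minus-marked spinal cord (SC) and brain. ENSRNOG00000046834 separates the marks in both tissues, and ENSRNOG00000047175 has no brain values because it did not pass the count filter there.

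All 41 genes called in brain had marks that did not overlap, which a call at this threshold favours, so this adds no support. The marks did not overlap for 834 of the genes tested (4.95%), where chance gives 2.86% on average over all splits. Genes are not independent, so single splits can lie well above that average. At an unadjusted p under 0.05, another split gave up to 2390 genes against 1539 for the real one. The excess over 2.86% therefore does not show an effect of mark in brain. The brain count depended on single libraries more than that of spinal cord. It was 8, 10 and 13 without plus-marked libraries 1, 2 and 3, and 24, 22 and 15 without minus-marked libraries 1, 3 and 4. Of the 41 genes, 7 were called in each of the 8 fits with 1 library left out, all 7 of them higher. The fall of ENSRNOG00000019176 missed the threshold without plus-marked library 1, 2 or 3 or minus-marked library 4, with an adjusted p of 0.0502, 0.0707, 0.0564 and 0.0553. Its adjusted p ranged from 5.03e-07 to 0.217 over all alternatives, while its brain log2 fold change stayed between -1.34 and -1.11. Within lane-like code L3, with 3 plus-marked and 2 minus-marked brain libraries, 29 genes were called, 23 higher and 6 lower. Within L1, with 1 and 2, 71 were called, 21 higher and 50 lower, the opposite balance to that of all brain libraries, the lone plus-marked library being taken to vary like the others. With the code as a term, 34 were called, 24 higher and 10 lower. DESeq2 called 203 genes, and 74 were called with no filter on low counts.

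The effect of mark differed between the tissues for 498 of 17823 genes tested in the joint fit, by the edgeR interaction term. Of these, 476 were also called in spinal cord and 2 in brain. The set held 176 genes that were higher in plus-marked spinal cord with a more positive effect there than in brain, and 300 that were lower with a more negative effect. None of the 4 genes named above was among them. The difference between spinal cord and brain in log2 fold change was 2.78 for ENSRNOG00000022242 (SE 0.87, adjusted p = 0.094), -2.98 for ENSRNOG00000047175 (SE 0.87, adjusted p = 0.0701), 0.08 for ENSRNOG00000046834 (SE 0.29, adjusted p = 0.91) and 0.40 for ENSRNOG00000019176 (SE 0.50, adjusted p = 0.712). The number of genes was 323, 318 and 229 without spinal cord plus-marked library 3 and minus-marked libraries 1 and 2. It was 233, 256, 215 and 261 without brain plus-marked libraries 1 to 4, and 220 and 313 without brain minus-marked libraries 3 and 4. DESeq2 gave 1137 genes, and 615 were called with the lane-like code as a term within each tissue, in spinal cord L24 against the other codes. The joint fit treated all 16 libraries as independent, although the same numbers occur in both tissues. With number as a block, 696 genes were called, 455 of them among the 498, and no values of the named genes were taken from that fit.

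Genes that changed in brain mostly changed the same way in spinal cord. Of the 40 brain-called genes tested in both tissues, 39 had the same direction in both. Called in both were 29 higher genes, where independent lists of these sizes would share 2.195, and 3 lower genes, where they would share 0.5547. No gene was called in opposite directions. Same-numbered libraries may share more than the mark, which the expected numbers do not allow for. These counts were not taken over libraries with no number in common. The shared higher genes had a median log2 fold change of 1.31 in spinal cord and 1.00 in brain, and 23 of the 29 changed more in spinal cord, a difference not tested for these genes as a set. Across all 16182 genes tested in both tissues, fold changes had a Pearson r of 0.286 and a Spearman rho of 0.19. With log2 CPM differences in place of fitted fold changes, r was 0.29, above the 0.212 that the other assignments of the brain marks reached at most (exact two-sided permutation p = 0.0286, the smallest they can give). The other assignments also part libraries that carry the same number in both tissues, so this p does not separate the mark from what same-numbered libraries share. Between subsets of 2 plus-marked and 2 minus-marked libraries per tissue with no number in common, mean r was 0.154 (0.0459 to 0.266). Between subsets of the same size with the same numbers in both tissues, mean r was 0.234 (0.137 to 0.341). The 0.154 is to be set against that value and not against the r of all libraries, which rests on larger groups. With the lane-like code as a term in both fits, again in spinal cord L24 against the other codes, r was 0.251.

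**Figure D3:**
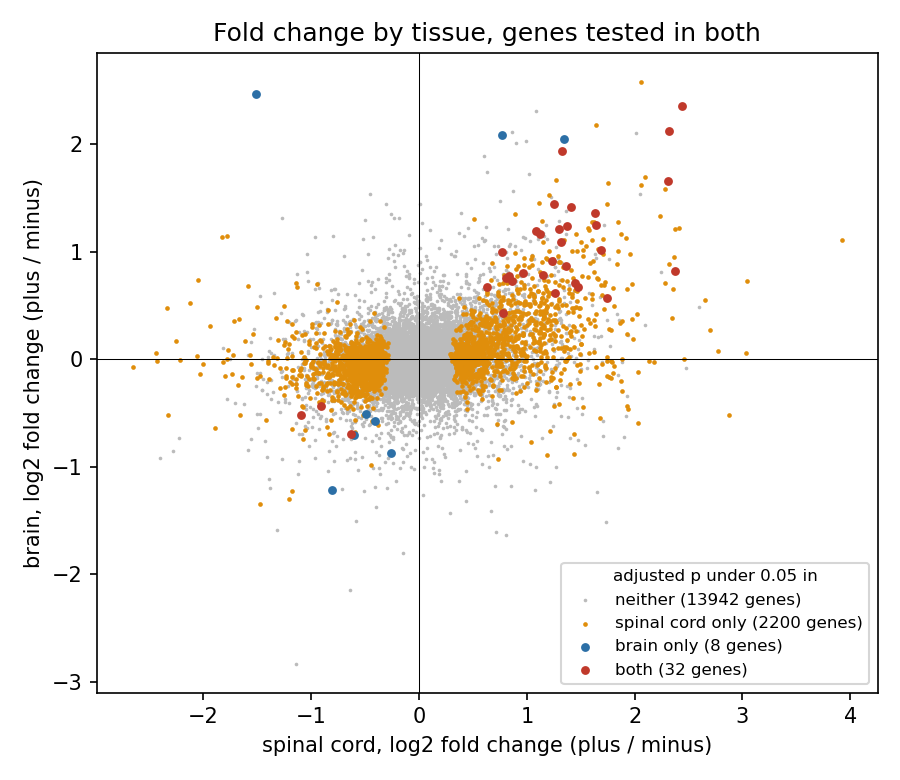
Each point is 1 of 16182 genes tested in both tissues, with its log2 fold change, plus over minus, in spinal cord on the horizontal and in brain on the vertical axis, coloured by where its adjusted p was under 0.05. The 32 genes past the threshold in both tissues lie in the upper right or lower left, and 2200 genes passed it in spinal cord and not in brain, which is not a test of a difference between the tissues.

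The genes called in spinal cord also leaned the same way in brain. The 1110 that were higher in spinal cord and tested in brain had a median brain log2 fold change of 0.14, and 71.3% of them were positive. The 1122 that were lower had a median of -0.05, and 64.3% of them were negative. In log2 CPM differences these medians were 0.141 and -0.0515, where other assignments of the brain marks reached up to 0.124 and 0.0497 in size (exact two-sided permutation p = 0.0286, the smallest they can give). The margins are small, the limit of shared numbers holds here too, and the medians were not computed over libraries with no number in common. With the correlation these medians make 3 tests, and Benjamini-Hochberg adjustment leaves each p at that value.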

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

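The tests of brain depth and of L24 against the other codes, both tests on brain minus-marked library 4 and the test of shared animals were set after related values had been seen, and the lane-like code was added as a term after the tables had been seen. The test with 1 library left out and those on other splits were set before their results were known. Combinations of a group of 4 libraries with a measure were examined for a value far from the other 3. Among the 26 combinations, 2 stood out, where chance gives about 1 in 20.

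The effect of mark differed between spinal cord and brain for 498 genes by the interaction term, and 2312 genes were called in spinal cord against 41 in brain. Lower depth in brain is argued against, since the median brain total was 1.59 times that of spinal cord. A single aberrant spinal cord library is also argued against: the lowest spinal cord count with 1 library left out was 1175, above the highest such brain count of 60. A difference between lane-like code L24 and the other codes as the whole cause is argued against, since with that term 2636 spinal cord genes were called, against 34 in brain with its code as a term. The term was to decide on the code as such, but it does not separate the other 4 codes, which hold 1 library each; among these, code and mark cannot be told apart. A tissue difference in the response to neuronal complex IV deficiency may underlie the pattern but was not tested apart from dissection, cell composition or other differences between the tables.

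For the counts at an adjusted p under 0.05, the real split gave the most genes in each of the 3 comparisons. No share smaller than 1 of 35 was possible, so chance is made less likely but cannot be excluded. The other splits mix the marks, so an effect of mark adds to the spread within their groups and lowers their counts. Of 35 splits of the spinal cord libraries 1, the real one, gave as many as 2312 genes (highest other 0 by edgeR, with at most 2248 genes at an unadjusted p under 0.05 against 5110). In brain 1 of 35 gave as many as 41 (highest other 2). For the interaction 1 of 35 gave 498 (highest other 0, with at most 1555 genes at an unadjusted p under 0.05 against 3440). For brain the real split did not give the most genes at an unadjusted p under 0.05. There 4 of 35 splits, the real one included, gave at least the real 1539 genes, the other 3 giving 2390, 2033 and 2011. Each of those 3 sets plus-marked libraries 1 and 2 with minus-marked library 2. The remaining splits that do so gave 1499 and 639 genes. On the first principal component of brain, which did not separate the marks, these libraries lay highest. Plus-marked libraries 1 and 2 were at 34.89 and 11.09, and minus-marked library 2 was at 11.94. The brain libraries thus hold a structure that does not follow the mark, but what it reflects was not tested.

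Brain minus-marked library 4 had 36.07% of its counts in the 10 most abundant brain genes, against 17.76% to 18.79% in the other 3 minus-marked libraries. The plus-marked brain libraries lay between these values, at 22.05% to 26.36%. One gene alone is argued against, because 10 of the 10 genes had a higher share than in every other minus-marked library, by 1.55 to 2.69 times their mean. For 7 of the 10 the share in library 4 was also above that in every plus-marked brain library. Low depth is argued against as well, since its total of 49806935 lay above the lowest of the others, 33105800. A difference in dissection or in RNA composition may remain, and no biological explanation was tested. Without this library 15 brain genes were called instead of 41, and with the 10 genes left out of library sizes 44 were.

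Spinal cord minus-marked library 2 had 20084 genes with a count, against 19914 to 19926 in the other 3. It was also the deepest spinal cord library, at 47597097 counts. The plus-marked spinal cord libraries ranged from 19032 to 20213 genes with a count, and the one with 20213 had a lower total of 40359757 counts.

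Fold changes in brain followed those in spinal cord, and libraries with the same number may come from one animal. Shared animals as the whole cause are argued against: in 36 of 36 pairings of 2 plus- and 2 minus-marked libraries per tissue with no number in common, the correlation exceeded that of both mixed splits of the same brain libraries. These pairings overlap and are not independent. The mean covariance was 0.0266 with no number in common and 0.0414 with the same numbers, which is consistent with a part that same-numbered libraries share beyond the mark.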

How the results depend on the processing

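The lane-like code, the 10 most abundant genes left out and thinning were chosen after seeing the data; the other settings were planned. RLE, upper-quartile scaling, a mean of at least 1 CPM, thinning and library sizes without the 10 most abundant genes moved the tissue counts by less than 1.5 times where run, and no named fold change or correlation changed sign. The near-even spinal cord balance (1171 higher, 1141 lower) turned to 1115 and 1237 without the 10 genes, 1051 and 1168 with no filter on low counts, 1301 and 1335 with L24 as a term, 396 and 693 in the other codes, 967 and 1070 without plus-marked library 1 and 717 and 746 without library 3. The brain balance turned to 21 and 50 within L1. Leaving out 1 library gave 1175 to 2114 genes in spinal cord, 8 to 60 in brain, 215 to 647 for the interaction and a correlation of 0.2351 to 0.3035 between tissues; fewer samples enter these fits. An absolute log2 fold change of at least 1 left 543 and 19 genes by construction. DESeq2 called 3299 spinal cord genes (1754 higher, 1545 lower), 203 brain genes and 1137 interaction genes. With no filter on low counts, 74 brain genes were called. The cause was not tested. Within lane-like codes, with fewer samples, 267 (L24) and 1089 (others) spinal cord genes and 71 (L1) brain genes were called. The correlation was 0.3363 with a mean of at least 1 CPM, 0.5005 over genes called in either tissue and 0.2513 with the code as a term (L24 against the others in spinal cord); the cause was not tested. No paired analysis was possible for the comparisons of mark because the columns carry no number shared between marks. Numbers are shared between tissues: with number as a block the interaction gave 696 genes, 455 of them among the 498. Deviations of same-numbered libraries correlated from -0.07482 to 0.2507, 6 of 8 above 0.1, and 7 of 8 libraries correlated best with their own number, a hint from the data and not from the design. Settings that need gene names (library sizes without mitochondrially encoded genes, the edited gene, gene lists) and all settings for early-stage spinal cord were not run. Thinned to the smallest library, 2218 spinal cord and 44 brain genes were called; which genes depth limits was not tested.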

Other observations

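In spinal cord the direction of the called genes varied with expression level. Tested genes were ranked by mean expression and divided into 4 groups of near-equal size. In the lowest group, up to 4.21 CPM, 242 genes were higher and 62 lower in plus-marked libraries. In the highest group, from 63.3 CPM, 305 were higher and 475 lower. In the groups between them the counts were 358 higher and 228 lower, then 266 higher and 376 lower. In brain, where 41 genes were called, the lowest group held 5 higher and 1 lower and the highest 4 higher and 3 lower. The groups between them held 18 higher and 2 lower, then 5 higher and 3 lower.

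The 10 most abundant genes took a larger share of the counts in brain than in spinal cord. Their share was 24.5% ± 2.15 in plus-marked and 22.7% ± 8.91 in minus-marked brain libraries, and 4.85% ± 0.623 and 5.52% ± 0.345 in spinal cord (SD, n = 4), each tissue having its own 10 genes. The minus-marked brain mean includes library 4 at 36.07%. The other minus-marked brain libraries, at 17.76% to 18.79%, all lay below the plus-marked ones, at 22.05% to 26.36%.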
